A study of Homo sapiens with 16 samples.

How the data were processed

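The series holds 16 RNA-seq libraries of xenograft tumours, 1 library per tumour, in 4 groups of 4: clean vehicle, clean STF, infected vehicle and infected STF. The labels give infection, treatment and a replicate number per tumour, and a sample code whose meaning they do not state. RNA was extracted with an RNeasy kit, and stranded libraries of total RNA were made after removal of ribosomal RNA.

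Each deposited file lists read counts per gene symbol, the unit being the raw count of reads that the authors assigned to each gene. The authors' notes name bcl2fastq, Trim Galore 0.4, STAR 2.6, Subread, featureCounts 1.4.6 and DESeq2, and the builds mm10, hg19 and GRCh37, without the order or role of each. The treatment of mouse reads is not given in the sources used here. The deposited files also hold a log2 column of counts that the authors normalized across libraries, which was looked at and not used here. In clean vehicle replicate 4 that column equals that of clean vehicle replicate 1, while the raw counts of the pair differ. The raw counts of replicates were tested for duplicated libraries, and the smallest chi-square per degree of freedom between libraries of a group was 19.4, far above that of copies of 1 library.

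The count tables hold 55765 genes, 8076 of them with 0 counts in all libraries. Totals ran from 10.3 to 65.8 M. PCR copies were not removed by molecular identifiers, so counting intervals cover counting error only. A reference annotation of a later build was used for gene names and gene classes, which it gave for 35572 genes, and for the exon lengths of marker and olfactory receptor genes, and not for positions.

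The main test was edgeR 4.0.16 (R 4.3.3) with limma 3.58.1: TMM factors, genes kept by filterByExpr (22632), a robust quasi-likelihood fit of all 16 libraries with 1 mean per group, and 5 contrasts. These were STF against vehicle in clean tumours, the same in infected tumours, the difference of both effects (infected minus clean), infected against clean under vehicle, and infected against clean under STF. The common dispersion was 0.0683. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. They measure the spread between samples, pooled over the 4 groups and not taken from the compared groups alone. With the compared groups alone, STF in clean tumours gave 8698 genes against 11554 in the shared fit. Infection under STF gave 3839 against 7414. Comparisons that share a group share its chance values. On simulated data with these depths, the test recovered 38 to 75% of genes changed 2-fold and 83 to 92% of those changed 4-fold, with 6 to 11 false calls per comparison. The simulation changed few genes and gave all groups the same spread. In the data many genes were called and clean STF tumours spread more widely, so these rates need not hold for them.

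Named genes followed a rule. Of the genes that passed, had a mean of at least 1 CPM over all libraries and did not overlap between the groups compared (this last not for the difference of effects), the 8 with the largest rise and the 8 with the largest fall were eligible, passing over clones, antisense transcripts, pseudogenes, small RNAs and provisional names. Eligible too were up to 4 members of each list with the smallest adjusted p, NAMPT, NAPRT1, NNMT and 4 other NAD enzymes, and, where fewer than 5 genes passed, the 5 with the smallest p. Levels are CPM with TMM scaling, and scores are means of log2 CPM with a prior count of 2.

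The 31 gene lists covered NAD biosynthesis, NAD-consuming enzymes, glycolysis, oxidative phosphorylation, mitochondrially encoded proteins, the integrated stress response, endoplasmic reticulum chaperones, hypoxia, G1/S, G2/M, histones, p53 targets, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory genes, pattern recognition, cholesterol, lipid synthesis, fatty acid oxidation, NRF2 targets, heat shock, lysosome and autophagy, ribosomal proteins, Wnt targets, intestinal differentiation, and markers of fibroblasts, endothelium, macrophages and neutrophils, lymphocytes and NK cells, erythroid cells, and skin, muscle and fat. Of 798 entries 796 matched the files, 50 through an older symbol. The lists were tested with camera at a preset correlation of 0.01, adjusted over 155 tests, of which 67 passed. With an estimated correlation 0 passed (smallest adjusted p 0.769), and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, passed 34. Scores, library totals and shares of counts were compared by exact two-sided permutation tests over 70 arrangements of 4 against 4 tumours, whose smallest p is 0.029.

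The alternatives were RLE size factors, library totals alone, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma voom with sample weights, the replicate number as a block, the sample code as a covariate, a fit of the compared groups alone, and leaving out each library in turn. Alternatives added after the data were seen were leaving out clean STF replicates 2 and 4, thinning every library to 10.3 M counts, and scaling to the summed counts of 30 zinc finger genes of 19p12, of which 11 passed the filter. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 made the tables, permutation tests and plots.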

Results

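RNA was sequenced from 16 tumours grown in nude mice from HCT116, a human colon carcinoma cell line. The grafted cells were clean, meaning free of bacteria, or carried Mycoplasma hyorhinis, a small bacterium without a cell wall that lives on host cells. Mice received vehicle or STF118804 (STF below), an inhibitor of NAMPT, the rate-limiting enzyme of NAD salvage from nicotinamide. The drug was injected under the skin at 15 mg per kg 2 times a day, starting at a tumour volume of 200 mm3 and ending after 2 weeks or at 1000 mm3. Infection and treatment were crossed, which gave 4 groups of 4 tumours: clean vehicle, clean STF, infected vehicle and infected STF. Each tumour gave 1 library of total RNA depleted of ribosomal RNA, counted per gene symbol over 55765 genes, of which 22632 passed the filter on low counts and were tested.

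The clean vehicle libraries (replicates 1, 3, 4 and 5) held 52.9, 51.5, 57.5 and 56.1 M counts (M, mega), and the clean STF libraries (replicates 1 to 4) held 36.2, 10.3, 38.7 and 19.8 M. The infected vehicle libraries (replicates 1, 2, 4 and 5) held 54.3, 65.8, 46.1 and 61.7 M, and the infected STF libraries (the same numbers) held 43.7, 38.2, 40.8 and 42.7 M. Totals were lower under STF in clean tumours (26.3 ± 13.6 against 54.5 ± 2.75 M, mean ± SD, n = 4) and in infected tumours (41.4 ± 2.40 against 57.0 ± 8.68 M). Both differences had an exact two-sided permutation p of 0.029, the smallest that 4 against 4 tumours allow, and an adjusted p of 0.114 over 24 such tests. Mitochondrially encoded genes took 2.86 ± 1.03% of the counts in clean STF tumours and 1.09 ± 0.28% in clean vehicle tumours (exact permutation p 0.029, adjusted 0.114). They took 1.29 ± 0.52% in infected STF and 0.88 ± 0.15% in infected vehicle tumours (exact permutation p 0.229). The first principal component held 72.2% of the variance and set clean STF tumours (86.9 to 249) apart from the other 12 (−83.3 to 11.6).

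Levels are given below as counts per M counts (CPM) with TMM scaling, as mean ± SD over 4 tumours, and changes as log2 fold change ± SE. Adjusted p-values of genes come from edgeR's quasi-likelihood test with the Benjamini-Hochberg correction. Gene lists, the tests of genes and lists and the rule for which genes are named were fixed before the data were examined. The tests on processed pseudogenes and on the zinc finger score by itself were chosen after the data were seen. Each list's set test is camera with a preset correlation, adjusted over 155 tests. Counts of list members are those past the threshold over all genes tested, and counts adjusted over the list alone were the same unless given. The files identify genes by symbol alone and give no positions, so none are printed.

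The first comparison asked what the NAMPT inhibitor did to tumours without bacteria. Clean STF tumours held more RNA of connective tissue, vessel, immune, muscle and fat genes than clean vehicle tumours, and less of genes of the cell cycle and the interferon response. The counts do not show whether the reads of a gene came from tumour cells or from mouse cells. POSTN, which encodes the matrix protein periostin, rose from 15.1 ± 2.09 to 406 ± 339 CPM (4.75 ± 0.47, adjusted p 5.82e-06). C1QB, a complement gene of macrophages, rose from 2.07 ± 0.463 to 23.0 ± 16.9 CPM (3.45 ± 0.38, adjusted p 5.83e-06). PCNA, the sliding clamp of DNA replication, fell from 219 ± 14.2 to 118 ± 22.0 CPM (−0.89 ± 0.15, adjusted p 0.000124), and SAMD9, an interferon-induced gene, from 313 ± 44.4 to 125 ± 42.8 CPM (−1.32 ± 0.20, adjusted p 4.74e-05). NAMPT itself, the target of the drug, measured 66.3 ± 5.87 and 78.8 ± 21.9 CPM and did not pass (0.25 ± 0.15, adjusted p 0.172), though it did without clean STF replicate 2 (0.41).

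In all, 5718 genes rose and 5836 fell. The split between both directions depended on the scaling: with libraries scaled to 30 zinc finger genes of 19p12, a primate-specific family that mouse RNA should rarely match, 12794 rose and 189 fell. That scaling was chosen after the data were seen and moved the median of all genes from −0.07 to 0.71, so falls below are falls relative to most other genes. With it 12 of 66 named genes lost their call and 4 turned sign, and not each of the 12 is marked below. DESeq2 called 8043 rises and 5094 falls.

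**Figure D1:**
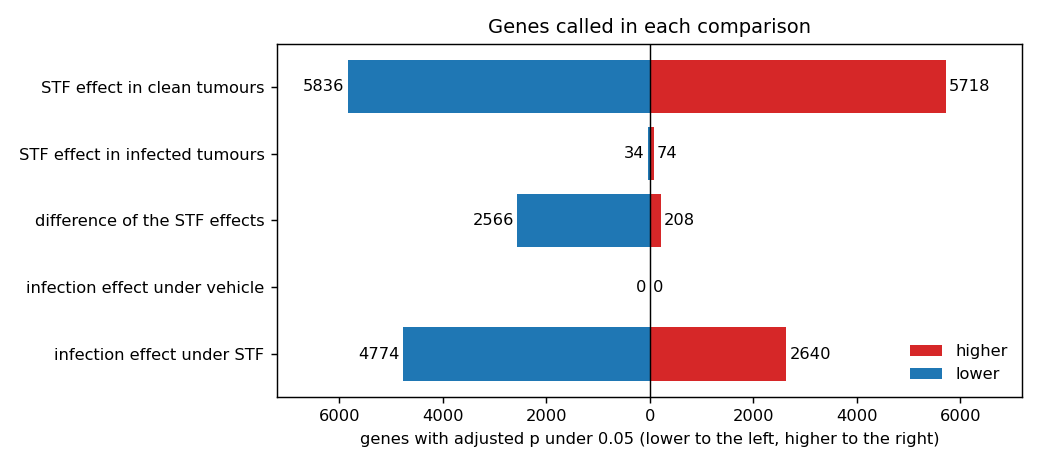
Number of genes called higher (bars to the right of 0) and lower (bars to the left of 0) in each of the 5 comparisons, by edgeR at an adjusted p of 0.05 over 22632 genes and 16 libraries. STF in clean tumours gave 11554 calls, STF in infected tumours 108 and infection under vehicle 0.

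The genes named next had the largest rises and falls among those with no overlap between the groups, which chance gives to 2.86% of genes. MYL4, an atrial and embryonic myosin light chain, rose from 0.257 ± 0.241 to 47.2 ± 40.5 CPM (7.51 ± 1.02, adjusted p 4e-05). The acute-phase genes HP (7.18 ± 0.95), which encodes haptoglobin, and SAA1 (6.94 ± 1.13) rose with the carboxylesterase CES1 (7.71 ± 1.41) and the transcription factor ZBTB16 (7.19 ± 0.91). HPR (6.92 ± 1.01) is a close paralog of HP, and the counts do not show which of the pair the reads came from. PCK1, an enzyme of glucose synthesis, rose by 7.01 ± 1.56 but did not pass without clean STF replicates 2 and 4, the 2 shallowest libraries (1.94). S100A9, a calcium-binding protein of neutrophils, had 3 counts over all clean vehicle libraries and 284 over all clean STF libraries, a ratio of 197 after scaling to library totals (95% exact Clopper-Pearson interval 66.6 to 959, which covers counting error only).

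The largest falls were in CYP24A1, the enzyme that breaks down active vitamin D, from 79.8 ± 40.5 to 5.50 ± 2.71 CPM (−3.80 ± 0.75, adjusted p 0.00084). GPR15, a receptor of lymphocyte homing, fell from 11.6 ± 9.13 to 1.46 ± 0.457 CPM (−2.96 ± 0.48), and WNT16, a secreted Wnt ligand, from 58.5 ± 15.5 to 15.0 ± 7.03 CPM (−1.97 ± 0.41). ZCCHC12 (−2.44 ± 0.43), SUN3 (−2.25 ± 0.39), the testis linker histone HIST1H1T (−2.06 ± 0.33), LONRF2 (−2.0 ± 0.41) and ZNF488 (−2.0 ± 0.31) fell too. LONRF2 no longer passed with the zinc finger scaling (−1.07).

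Markers of cell types other than the grafted epithelium rose together. All 18 fibroblast markers rose (median 4.48, camera adjusted p 3.77e-17, adjusted p = 0.769 with an estimated correlation). PDGFRA, a growth factor receptor, rose by 5.62 ± 0.55 and the collagen gene COL5A1 by 4.76 ± 0.49. Of 16 macrophage and neutrophil markers all rose (median 3.56, camera adjusted p 3.17e-11, adjusted p = 0.769 with an estimated correlation). The integrin ITGAM rose by 3.32 ± 0.39. Of 12 endothelial markers 11 rose and 1 fell (median 3.37, camera adjusted p 4.46e-05, adjusted p = 0.769 with an estimated correlation). The junction protein CDH5 rose by 4.33 ± 0.52 and the receptor TEK by 4.46 ± 0.59. Of 14 skin, muscle and fat markers 10 rose and 0 fell, or 11 adjusted over the list alone (median 4.19, camera adjusted p 0.000217, adjusted p = 0.769 with an estimated correlation). Among these the fatty acid carrier FABP4 rose by 6.47 ± 1.03 and the basal keratin KRT5 from 23.4 ± 6.75 to 167 ± 109 CPM (2.83 ± 0.39). The 4 measured erythroid markers rose (median 4.27, camera adjusted p 0.164), although 1 passed without the 2 shallowest libraries. Of 7 lymphocyte and NK markers 3 rose (median 1.11, camera adjusted p 0.321), with 1 fall adjusted over the list alone. The mean log2 CPM of the fibroblast markers was 7.54 ± 1.12 in clean STF and 3.47 ± 0.13 in clean vehicle tumours (n = 4, exact permutation p 0.029).

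**Figure D2:**
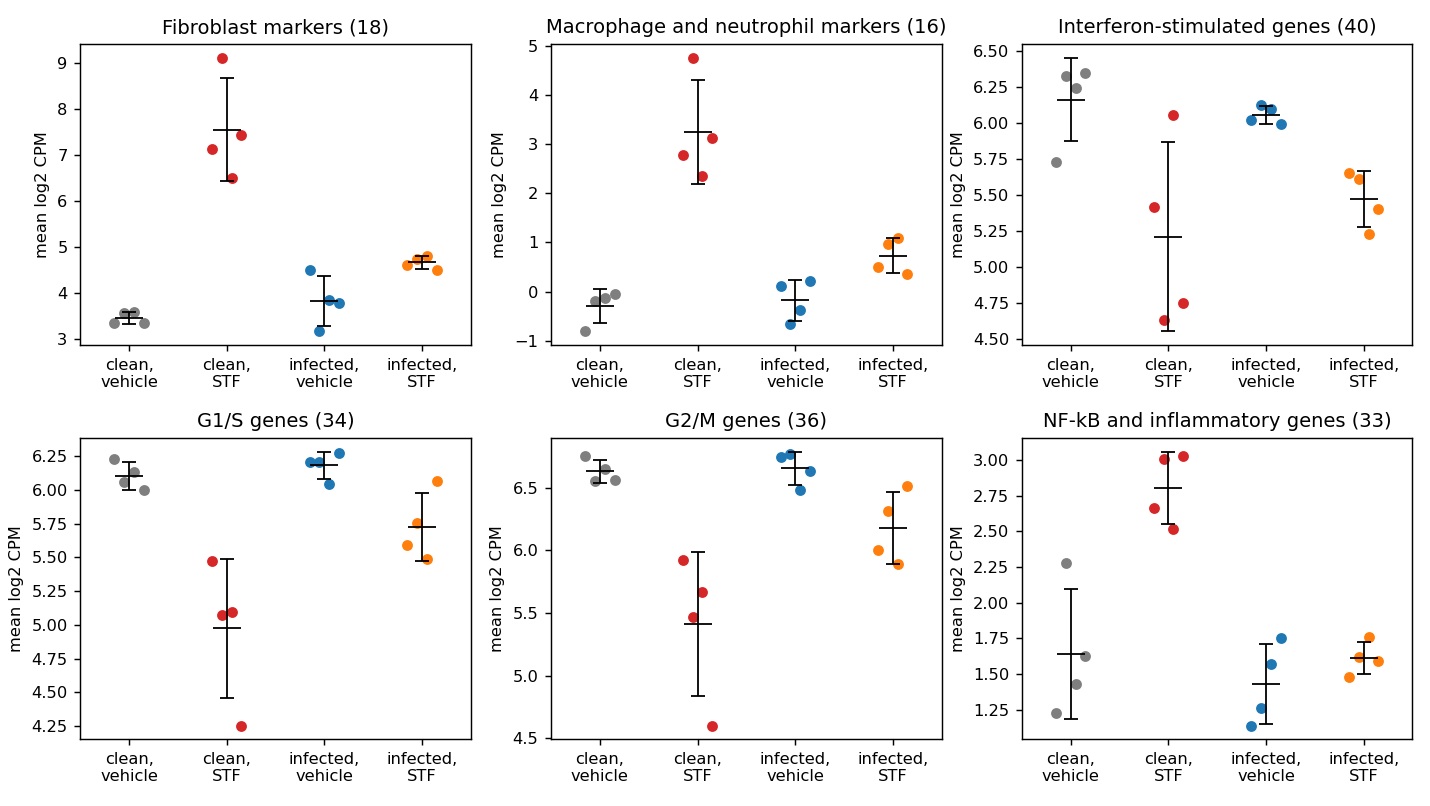
Mean log2 CPM of 6 gene lists in each of the 16 tumours (points), with the mean and SD of each group of 4 (bars). Fibroblast markers stood at 7.54 ± 1.12 in clean STF tumours against 3.47 ± 0.13 in clean vehicle tumours, while the G1/S, G2/M and interferon lists were lower in STF than in vehicle tumours.

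Processed pseudogenes rose in the same tumours. Of 1358 processed pseudogenes, reverse-transcribed copies of mRNAs, 1060 rose and 29 fell (median 3.71), and their mean log2 CPM went from −1.56 ± 0.10 to 0.94 ± 0.84 (n = 4, exact permutation p 0.029). Copies of ribosomal protein genes rose in 224 of 278 cases and fell in 3 (median 4.15). Long intergenic non-coding RNAs rose in 35 and fell in 40 of 236 cases, and their score did not pass (0.024, exact permutation p 0.857). The mean log2 CPM of the zinc finger genes fell by 0.70, from 3.23 ± 0.11 to 2.52 ± 0.36 (n = 4, exact permutation p 0.029).

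**Figure D3:**
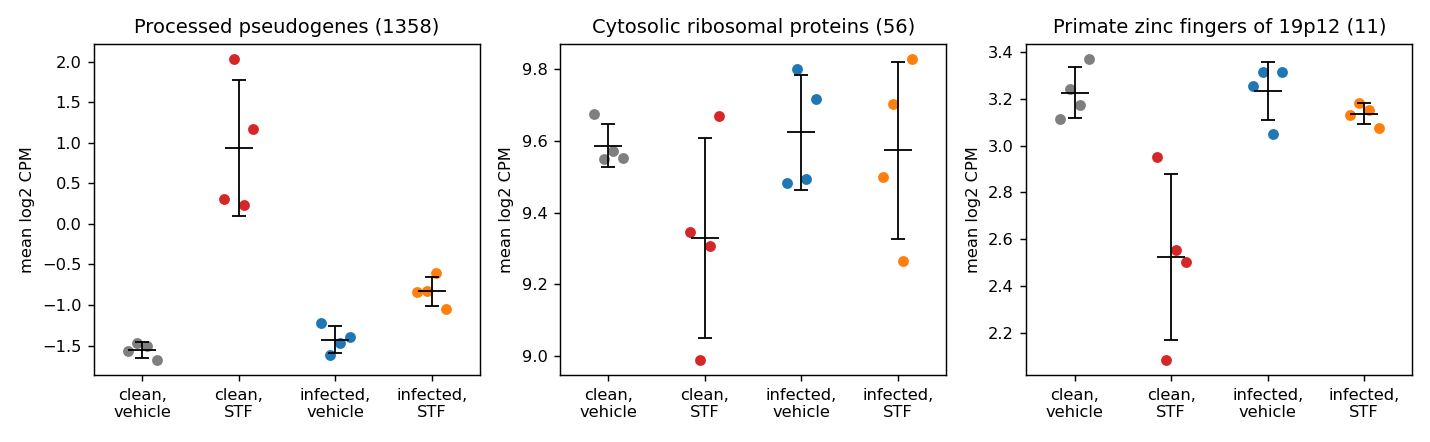
Mean log2 CPM of processed pseudogenes, cytosolic ribosomal protein genes and primate zinc finger genes in each of the 16 tumours (points), with the mean and SD of each group of 4. Processed pseudogenes were at 0.94 ± 0.84 in clean STF and −1.56 ± 0.10 in clean vehicle tumours, and zinc fingers at 2.52 ± 0.36 and 3.23 ± 0.11.

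Cell cycle genes fell almost as a block beside that fall of the zinc fingers. Of 34 G1/S genes 33 fell (median −1.09, camera adjusted p 2.37e-13, adjusted p = 0.769 with an estimated correlation). The cyclin CCNE2 fell by 1.03 ± 0.14 and the histone mRNA binder SLBP by 0.82 ± 0.11. All 36 G2/M genes fell (median −1.17, camera adjusted p 3.47e-14, adjusted p = 0.769 with an estimated correlation). The centromere histone CENPA fell from 18 ± 2.6 to 6.26 ± 2.81 CPM (−1.50 ± 0.24), KIF20B by 1.12 ± 0.16 and ECT2 by 1.03 ± 0.15. Under the zinc finger scaling 1 G1/S gene and 3 G2/M genes fell (medians −0.31 and −0.38), and PCNA (−0.08), CCNE2 (−0.23), SLBP (−0.05), KIF20B (−0.35) and ECT2 (−0.27) did not pass. Replication-dependent histones split, with 8 rising and 17 falling of 25, a median of −1.28, a mean of 0.06 and a camera call downwards (adjusted p 0.0197, adjusted p = 0.804 with an estimated correlation) that was lost without clean STF 3 (camera adjusted p 0.0901). HIST1H2AC fell from 285 ± 11.8 to 117 ± 39.3 CPM (−1.28 ± 0.19), and HIST1H4I rose from 7.52 ± 1.25 to 151 ± 155 CPM (4.31 ± 0.56).

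Interferon-stimulated genes fell in 28 of 40 cases and rose in 0, or 29 falls adjusted over the list alone (median −0.85, camera adjusted p 5.21e-07, adjusted p = 0.769 with an estimated correlation). The antiviral genes IFIT5 (−1.31 ± 0.23) and PLSCR1 (−0.95 ± 0.19) were among them. Without the 2 shallowest libraries 13 fell and 1 rose, and under the zinc finger scaling 2 fell and 2 rose. Antigen presentation genes rose in 3 and fell in 6 of 20 cases (median −0.18, camera adjusted p 0.294).

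More inflammatory genes rose than fell beside the markers of white blood cells, while pattern recognition genes did not pass as a set. Of 33 NF-kB and inflammatory genes 16 rose and 3 fell, or 17 and 3 adjusted over the list alone (median 0.59, camera adjusted p 0.0213, adjusted p = 0.769 with an estimated correlation). The cytokine gene IL1B rose from 0.438 ± 0.569 to 23.1 ± 15.2 CPM (5.72 ± 0.93), the granulocyte growth factor CSF3 by 4.54 ± 0.69 and the NF-kB inhibitor NFKBIA from 79.1 ± 26.3 to 206 ± 66.3 CPM (1.38 ± 0.23). Of 24 pattern recognition genes 7 rose and 5 fell (median 0.14, camera adjusted p 0.504). CD14, a receptor for bacterial products, rose by 5.21 ± 0.60 and TLR4 by 4.54 ± 0.52. Lysosome and autophagy genes rose in 12 of 26 cases and fell in 0 (median 0.29, camera adjusted p 0.0357, adjusted p = 0.769 with an estimated correlation). The protease CTSD rose by 0.88 ± 0.15 and WIPI1 by 0.85 ± 0.15. The set calls of both the inflammatory and the lysosome list were lost without the 2 shallowest libraries (camera adjusted p 0.113 and 0.251). The absence of 1 library also ended the inflammatory call (clean vehicle 1 or 4, or clean STF 2; camera adjusted p 0.0588 to 0.0849) and the lysosome call (any clean vehicle library, clean STF 2 or 3; 0.0621 to 0.11).

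Of 19 measured NAD biosynthesis genes 7 rose and 3 fell, with a median of −0.04, a mean of 1.16 and a camera adjusted p of 0.546. NNMT, which methylates nicotinamide and is abundant in liver and fibroblasts, rose from 0.0797 ± 0.0439 to 2.67 ± 2.87 CPM (4.91 ± 0.73), and the muscle kinase NMRK2 by 6.47 ± 1.02. NAPRT1, which starts the deamidated route from nicotinic acid, fell from 71.1 ± 8.40 to 48.9 ± 11.4 CPM (−0.53 ± 0.15, adjusted p 0.0059), and NMNAT1, a nuclear enzyme that joins NMN or its deamidated form to adenylate, from 14.4 ± 0.491 to 9.29 ± 2.27 CPM (−0.62 ± 0.17, adjusted p 0.00532). The sign of both turned with the zinc finger scaling (0.23 and 0.15), and NAPRT1 did not pass without the 2 shallowest libraries (−0.27). Of 24 NAD-consuming enzymes 4 rose and 10 fell, or 5 and 10 adjusted over the list alone (median −0.24 but 0.59 with the zinc finger scaling, camera adjusted p 0.208). PARP1, which uses NAD in DNA repair, fell by 0.99 ± 0.19 and the mitochondrial deacetylase SIRT3 by 0.87 ± 0.17, and neither passed with that scaling (−0.18 and −0.10).

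Nuclear and mitochondrial genes of respiration moved apart. Of 52 nuclear-encoded oxidative phosphorylation genes 22 fell and 1 rose (median −0.31, which turned to 0.47 with the zinc finger scaling, camera adjusted p 0.00361, adjusted p = 0.804 with an estimated correlation). NDUFB8 fell by 0.66 ± 0.13 and UQCRFS1 by 0.59 ± 0.12, and that scaling turned both (0.12 and 0.21). Of 13 mitochondrially encoded genes 10 rose, or 11 adjusted over the list alone (median 1.30, camera adjusted p 0.00416, adjusted p = 0.769 with an estimated correlation), and 5 without the 2 shallowest libraries. MT-ND4 rose by 1.74 ± 0.32 and MT-ND5 by 1.62 ± 0.31. Cytosolic ribosomal protein genes fell in 4 of 56 cases, or 0 adjusted over the list alone (median −0.25, which turned to 0.54 with the zinc finger scaling, camera adjusted p 0.0152, adjusted p = 0.865 with an estimated correlation), a call lost without clean STF 2 (camera adjusted p 0.117). Of 24 glycolysis genes 1 rose and 6 fell (median −0.11, camera adjusted p 0.216). Of 21 fatty acid oxidation genes 4 rose and 4 fell (median −0.11, mean 0.57, camera adjusted p 0.727).

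Stress genes were mixed. Of 37 amino acid and integrated stress response genes 11 rose and 13 fell (median −0.05, mean 0.34, camera adjusted p 0.882). CEBPB rose by 1.16 ± 0.16, NUPR1 by 2.97 ± 0.44 and CBS, an enzyme of cysteine synthesis, by 3.55 ± 0.56. Endoplasmic reticulum chaperone genes rose in 7 of 20 cases and fell in 0, or 6 adjusted over the list alone (median 0.12, camera adjusted p 0.133). HSPA5, the main chaperone of that compartment, rose from 390 ± 43.4 to 880 ± 318 CPM (1.17 ± 0.21), with DNAJB9 (1.37 ± 0.21) and EDEM1 (1.34 ± 0.19). NRF2 targets rose in 10 and fell in 3 of 25 cases, or 10 and 4 adjusted over the list alone (median 0.14, camera adjusted p 0.421). The haem-degrading HMOX1 rose by 1.52 ± 0.16, and the glutathione reductase GSR fell by 1.0 ± 0.15. Hypoxia genes rose in 6 and fell in 3 of 26 cases, or 5 and 2 adjusted over the list alone (median 0.06, camera adjusted p 0.738). Of 28 p53 targets 5 rose and 7 fell (median −0.17, camera adjusted p 0.503). Of 16 heat shock genes 1 rose and 4 fell, or 1 and 1 adjusted over the list alone (median −0.07, mean 0.21, camera adjusted p 0.542).

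Of 20 fatty acid and lipid synthesis genes 6 rose and 1 fell, or 5 and 1 adjusted over the list alone (median 0.14, camera adjusted p 0.607). The phosphatidate phosphatase LPIN1 rose by 1.33 ± 0.17, and the desaturase FADS1 fell by 0.83 ± 0.13. Of 25 cholesterol genes 3 rose and 5 fell (median −0.02, camera adjusted p 0.359). Wnt targets rose in 3 and fell in 8 of 17 cases, or 3 and 9 adjusted over the list alone (median −0.45 but 0.32 with the zinc finger scaling, mean 0.10, camera adjusted p 0.312). LGR5, a stem cell receptor, rose by 4.38 ± 0.52, and AXIN2, a feedback inhibitor, fell by 1.16 ± 0.20. Of 13 intestinal differentiation genes 5 rose and 4 fell, or 5 and 5 adjusted over the list alone (median 0.73, while camera ranked the list downwards, adjusted p 0.749).

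The second comparison asked what STF did to infected tumours. Here 74 genes rose and 34 fell. LPIN1 rose from 25.3 ± 2.75 to 56.1 ± 11.6 CPM (1.15 ± 0.17, adjusted p 0.0145), and KRT16, a keratin of stressed and wounded epidermis, from 6.65 ± 1.21 to 74.0 ± 31.7 CPM (3.48 ± 0.60, adjusted p 0.0333). LCN2, which binds bacterial iron carriers, fell from 6.12 ± 1.88 to 1.88 ± 0.226 CPM (−1.70 ± 0.33, adjusted p 0.0361), and TLR3, a sensor of double-stranded RNA, from 11.2 ± 1.8 to 5.18 ± 0.540 CPM (−1.12 ± 0.22, adjusted p 0.0361). NAMPT (59.7 ± 3.95 and 58.6 ± 5.76 CPM, −0.03 ± 0.15, adjusted p 0.928) and NAPRT1 (80.4 ± 4.41 and 74.1 ± 9.85 CPM, −0.12 ± 0.15, adjusted p 0.647) did not pass.

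Among the other large rises were PTX3, a soluble pattern recognition protein (3.66 ± 0.69), the interleukin receptor chain IL12RB2 (3.08 ± 0.48), the adhesion molecule CHL1 (2.80 ± 0.58) and the cytokine IL16 (2.72 ± 0.43). MGAM, a starch-digesting enzyme (2.59 ± 0.36), COL20A1 (2.57 ± 0.33, adjusted p 0.00993) and the growth factor FGF1 (2.43 ± 0.43) rose too. Falls were seen in PADI3 (−1.51 ± 0.33), CXXC4, an inhibitor of Wnt signalling (−1.43 ± 0.26), KIAA0319 (−1.29 ± 0.26), SH3RF2 (−1.18 ± 0.22), APOLD1 (−1.16 ± 0.19) and GPRIN3 (−1.04 ± 0.19). Among members of the lists, CBS rose by 3.01 ± 0.53, the p53 target PLK3 by 0.68 ± 0.14 and TLR9 by 1.4 ± 0.27.

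As sets, proliferation and interferon genes lay lower in infected STF tumours by camera, with 0 members past the threshold over all genes. In fry 0 lists passed downwards in this comparison and 1 upwards. Interferon-stimulated genes were below vehicle in 39 of 40 cases, and 19 fell adjusted over the list alone (median −0.61, camera adjusted p 5.01e-12, adjusted p = 0.769 with an estimated correlation). MX1, an antiviral GTPase, measured −1.02 ± 0.22 (adjusted p 0.0512) and EPSTI1 −0.73 ± 0.20 (adjusted p 0.0867). The mean log2 CPM of the list was 5.47 ± 0.20 against 6.06 ± 0.06 (n = 4, exact permutation p 0.029), and the difference relative to the zinc fingers was −0.49 (exact permutation p 0.029). Among G1/S genes 11 of 34 fell adjusted over the list alone (median −0.47, camera adjusted p 4e-11, adjusted p = 0.769 with an estimated correlation). CCNE2 measured −0.50 ± 0.14 (adjusted p 0.0871) and PCNA −0.47 ± 0.15 (adjusted p 0.12). Among G2/M genes 4 of 36 fell adjusted over the list alone (median −0.49, camera adjusted p 1.04e-10, adjusted p = 0.769 with an estimated correlation). ECT2 measured −0.65 ± 0.15 (adjusted p 0.057). The mean of the G1/S and G2/M scores was 5.95 ± 0.27 against 6.42 ± 0.11 (n = 4, exact permutation p 0.057), with overlap between the groups. Relative to the zinc fingers it differed by −0.37 (exact permutation p 0.114). Histones fell in 15 of 25 cases adjusted over the list alone (median −0.75, camera adjusted p 5.74e-06, adjusted p = 0.769 with an estimated correlation). HIST1H2AC measured −0.64 ± 0.19 (adjusted p 0.107). Antigen presentation genes were lower in 18 of 20 cases (median −0.46, camera adjusted p 0.000137, adjusted p = 0.769 with an estimated correlation).

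The metabolic and stress lists named next also had 0 members past the threshold over all genes. Nuclear-encoded oxidative phosphorylation genes (median −0.18, camera adjusted p 0.000169, adjusted p = 0.769 with an estimated correlation) and glycolysis genes (median −0.15, camera adjusted p 0.00781, adjusted p = 0.769 with an estimated correlation) lay lower, and both turned to 0.01 and 0.05 with the zinc finger scaling. Hypoxia genes lay lower and 5 of 26 fell adjusted over the list alone (median −0.27, camera adjusted p 0.00781, adjusted p = 0.769 with an estimated correlation). The collagen-modifying PLOD2 measured −0.75 ± 0.17 (adjusted p 0.0644) and the oxygen sensor EGLN1 −0.40 ± 0.10 (adjusted p 0.0764). Fatty acid oxidation genes lay lower (median −0.21, camera adjusted p 0.0194, adjusted p = 0.769 with an estimated correlation). Heat shock genes were higher in 14 of 16 cases (median 0.34, camera adjusted p 0.00755, adjusted p = 0.769 with an estimated correlation). BAG3 measured 0.49 ± 0.16 (adjusted p 0.128). Mitochondrially encoded genes lay higher (median 0.53, camera adjusted p 0.0042, adjusted p = 0.769 with an estimated correlation). The calls of hypoxia genes (without infected STF 2, camera adjusted p 0.0758), fatty acid oxidation genes (without infected STF 4, 0.0779) and heat shock genes (without infected vehicle 4 or infected STF 5, 0.0521 and 0.185) were lost on leaving out a single library. Cholesterol genes did not pass (median 0.24, camera adjusted p 0.0593). Nor did NAD biosynthesis genes (median 0.06, camera adjusted p 0.761, 1 rise and 1 fall adjusted over the list alone), with NMRK2 at 1.82 ± 0.87 (adjusted p 0.238).

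Of the 6 lists of markers of other cell types, 3 were called as sets in infected tumours. All 18 fibroblast markers were higher (median 0.69, camera adjusted p 3.02e-05, adjusted p = 0.769 with an estimated correlation). MMP2 measured 1.61 ± 0.50 (adjusted p 0.12) and PDGFRA 1.41 ± 0.48 (adjusted p 0.139). Macrophage and neutrophil markers rose in 3 of 16 cases adjusted over the list alone (median 0.83, camera adjusted p 6.8e-05, adjusted p = 0.769 with an estimated correlation), with ITGAM at 1.66 ± 0.37 (adjusted p 0.057). Skin, muscle and fat markers were higher in 14 of 14 cases (median 1.77, camera adjusted p 0.000295, adjusted p = 0.769 with an estimated correlation). Endothelial (median 0.32, camera adjusted p 0.249), lymphocyte and NK (0.07, camera adjusted p 0.792) and erythroid markers (0.20, camera adjusted p 0.722) did not pass. The processed pseudogene score was higher by 0.60 (n = 4, exact permutation p 0.029), while the zinc finger score was 3.14 ± 0.05 against 3.23 ± 0.13 (n = 4, exact permutation p 0.2).

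The count of 108 depended on the fit and on single libraries: at an unadjusted p under 0.05 it was 4856, limma voom called 4456 genes, DESeq2 1150, edgeR on the 8 infected libraries alone 3539 and edgeR with the sample code as a covariate 723, and limma voom, DESeq2 and edgeR on the 8 infected libraries alone shared 108, 104 and 102 of the genes in direction. Leaving out infected vehicle replicate 1, 4 or 5 left 0 genes, infected vehicle 2 left 8, infected STF 2 left 14 and infected STF 4 left 4; a stricter filter left 46, thinning all libraries to the smallest total left 7, and both library totals alone (57 rises, 7 falls) and the zinc finger scaling (45 rises, 0 falls) moved the split.

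**Figure D4:**
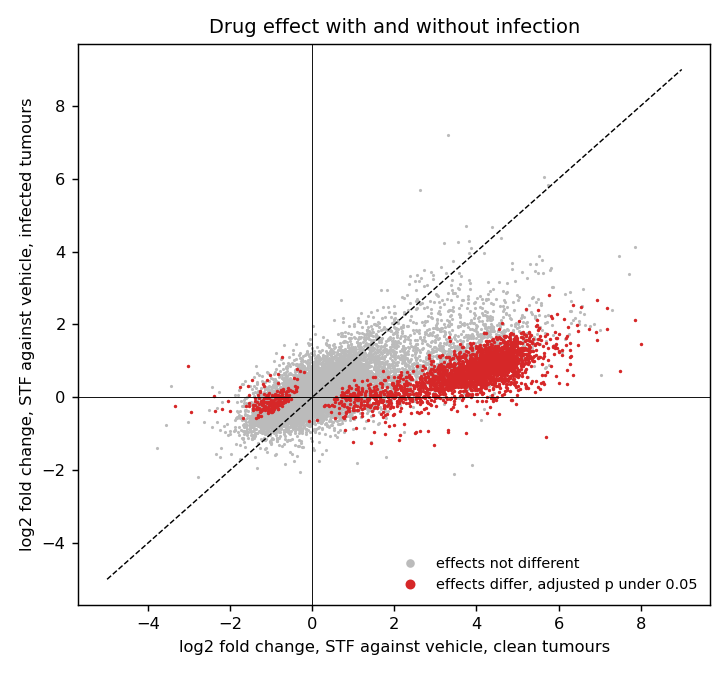
Log2 fold change of each of 22632 genes under STF in clean tumours (horizontal axis) and in infected tumours (vertical axis), with genes whose effects differed in red. Most genes lie nearer to 0 on the vertical axis, with a slope of 0.27 and a Pearson r of 0.73 across genes.

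The third comparison asked where the effect of STF differed with infection, the question named in the series' design. In 2774 genes it did: 2566 changed less upwards or more downwards in infected tumours, and 208 the other way. Protein-coding genes made up 1039 of the 2566 and 142 of the 208. How far a different share of mouse RNA in clean STF tumours entered these differences was not tested. The difference, infected minus clean, was −6.78 ± 1.25 for MYL4 (adjusted p 0.00332), −5.62 ± 0.96 for the matrix gene TNN and −5.47 ± 1.65 for the muscle carbonic anhydrase CA3. It was −5.37 ± 1.45 for SAA1, −5.36 ± 0.92 for LRRN1, −5.32 ± 1.18 for ZBTB16, −5.18 ± 1.44 for the muscle protein MYBPC1 and −5.17 ± 1.41 for PLIN1, which coats fat droplets. It was positive for GPR15 (2.55 ± 0.63, adjusted p 0.0134), the lipoprotein receptor gene LRP1B (1.94 ± 0.28, adjusted p 0.00265), PEG10 (1.61 ± 0.36), the guidance cue SEMA3A (1.54 ± 0.27), the BMP target ID3 (1.45 ± 0.32), GLIPR1L1 (1.41 ± 0.31), the glutathione transferase GSTA4 (1.36 ± 0.39) and TMSB15A (1.19 ± 0.38). Without the 2 shallowest libraries CA3, SAA1, MYBPC1, PLIN1, GPR15 and TMSB15A did not pass, and leaving out 1 library ended the calls of CA3, SAA1, MYBPC1, PLIN1, GSTA4 and TMSB15A. NNMT differed (−4.40 ± 1.03, adjusted p 0.00865), while NAMPT (−0.28 ± 0.21, adjusted p 0.417) and NAPRT1 (0.42 ± 0.21, adjusted p 0.205) did not pass.

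Counts of members here are those past the threshold with a negative difference. These were all 18 fibroblast markers (median −3.81, camera adjusted p 5.23e-24, adjusted p = 0.769 with an estimated correlation), and 10 of 12 endothelial markers, or 11 adjusted over the list alone (median −2.91, camera adjusted p 5.21e-07, adjusted p = 0.769 with an estimated correlation). They were also 14 of 16 macrophage and neutrophil markers, or 15 adjusted over the list alone (median −2.96, camera adjusted p 1.45e-11, adjusted p = 0.769 with an estimated correlation). Of 14 skin, muscle and fat markers 13 had a negative difference but 2 passed, or 3 adjusted over the list alone (median −2.21, camera adjusted p 0.00141, adjusted p = 0.769 with an estimated correlation). Lymphocyte and NK (median −0.86, camera adjusted p 0.265, 1 of 7 past the threshold) and erythroid markers (−3.95, camera adjusted p 0.0647, 0 of 4, or 3 adjusted over the list alone) did not pass as sets. Processed pseudogenes went with the lists that did, with 752 of 1358 past the threshold as negative and 2 as positive. Inflammatory genes passed in 4 of 33 cases, or 7 adjusted over the list alone (median −0.47, camera adjusted p 0.00782, adjusted p = 0.769 with an estimated correlation), and lysosome genes in 4 of 26 (median −0.34, camera adjusted p 0.0067, adjusted p = 0.769 with an estimated correlation).

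Cell cycle lists fell less in infected than in clean tumours as sets, beside a smaller fall of the zinc fingers. The median difference was 0.62 for G1/S genes with 0 of 34 past the threshold (camera adjusted p 2.27e-08, adjusted p = 0.769 with an estimated correlation) and 0.68 for G2/M genes with 1 of 36, or 0 adjusted over the list alone (camera adjusted p 1.62e-09, adjusted p = 0.769 with an estimated correlation), and these medians shrank to 0.03 and 0.10 with the zinc finger scaling. Cholesterol genes (0.23, camera adjusted p 0.0118) and heat shock genes (0.41, camera adjusted p 0.0148) had positive medians that turned to −0.30 and −0.17 with that scaling (adjusted p = 0.769 with an estimated correlation for both). Ribosomal protein genes (0.20, camera adjusted p 0.0107, adjusted p = 0.864 with an estimated correlation) and p53 targets (0.23, camera adjusted p 0.0327, adjusted p = 0.804 with an estimated correlation) turned to −0.40 and −0.32. Interferon genes (0.24, camera adjusted p 0.0173, adjusted p = 0.83 with an estimated correlation) turned to −0.32, and to −0.17 without the 2 shallowest libraries. Hypoxia genes were negative (median −0.26, 1 of 26 past the threshold, camera adjusted p 0.0375, adjusted p = 0.804 with an estimated correlation). Leaving out 1 library ended 6 of these calls: hypoxia (6 libraries in turn, camera adjusted p 0.0853 to 0.199), p53 (clean STF 2 or 4, infected STF 5; 0.0587 to 0.146), interferon (clean STF 2 or 4; 0.196 and 0.129), ribosomal protein (clean STF 2, infected STF 5; 0.143 and 0.0735), cholesterol (clean STF 2; 0.12) and heat shock genes (clean STF 3; 0.0512).

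Where both effects were called they pointed the same way. Of the 74 genes that rose in infected tumours 69 rose in clean tumours, with 18.7 expected of independent calls, and of the 34 that fell 32 fell, with 8.77 expected; 0 went opposite ways. In separate fits of 8 libraries, 1328 genes rose in both (345 expected) and 1156 fell in both (310 expected), while 6 and 2 went opposite ways. Across 22632 genes, which are not independent replicates, the effects had a Pearson r of 0.73, a Spearman rho of 0.75 and a slope of 0.27. A response score, the mean log2 CPM of the 4807 genes that rose minus that of the 3891 genes that fell in the 8 clean libraries, was −4.11 ± 0.32 in infected STF and −5.09 ± 0.20 in infected vehicle tumours, 0.98 higher (n = 4, exact permutation p 0.029). The rising part was higher by 0.64 and the falling part lower (−0.34), each with an exact permutation p of 0.029, though relative to the zinc fingers the falling part was −0.24 (exact permutation p 0.086) and did not pass. Whether the rising part came from tumour or mouse RNA was not tested. Processed pseudogenes, which rose in clean STF tumours, also scored 0.60 higher in infected STF than in infected vehicle tumours (n = 4, exact permutation p 0.029). The count of 2774 went to 5359 without clean STF replicate 1 and to 1383 after thinning, and the zinc finger scaling gave 8 positive and 4400 negative genes.

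The fourth comparison asked what infection did without the drug. No gene passed in edgeR: 0 rose and 0 fell, 409 were under an unadjusted p of 0.05, DESeq2 called 0 genes, limma voom 8 and edgeR on the 8 vehicle libraries alone 5. The 5 genes with the smallest p, none of which passed (adjusted p 1.0), were VCAN, a matrix proteoglycan (72.3 ± 8.51 CPM in clean and 42.6 ± 4.59 in infected tumours, −0.76 ± 0.14), ANXA10 (25.7 ± 2.41 and 42.3 ± 7.24 CPM, 0.72 ± 0.15), CILP (0.90 ± 0.20), SAMD9L (11.2 ± 2.58 and 5.95 ± 1.49 CPM, −0.91 ± 0.21) and RP11-817J15.3 (−1.77 ± 0.41). NAMPT (−0.15 ± 0.15) and NAPRT1 (0.18 ± 0.15) did not pass.

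Small shifts of whole lists were called by camera with the preset correlation, with 0 members past the threshold over all genes. In fry 0 of 31 lists passed in this comparison (smallest fry adjusted p 0.15). Histone genes were higher in infected tumours in 24 of 25 cases (median 0.30, camera adjusted p 2.17e-06, adjusted p = 0.769 with an estimated correlation), and all 18 fibroblast markers were higher (median 0.46, camera adjusted p 1.32e-05, adjusted p = 0.769 with an estimated correlation). All 13 mitochondrially encoded genes were lower (median −0.32, camera adjusted p 6.76e-06, adjusted p = 0.769 with an estimated correlation), as were 19 of 20 endoplasmic reticulum chaperones (median −0.11, camera adjusted p 0.000241, adjusted p = 0.769 with an estimated correlation). Inflammatory genes (median −0.20, camera adjusted p 0.00173) and antigen presentation genes (median −0.13, camera adjusted p 0.00738) lay lower (adjusted p = 0.769 with an estimated correlation for both). The remaining calls were G1/S genes (median 0.09, camera adjusted p 0.0173, adjusted p = 0.828 with an estimated correlation), heat shock genes (−0.09, camera adjusted p 0.0213, adjusted p = 0.802 with an estimated correlation), ribosomal protein genes (0.06, camera adjusted p 0.025, adjusted p = 0.867 with an estimated correlation) and oxidative phosphorylation genes (0.06, turning to −0.01 with the zinc finger scaling, camera adjusted p 0.0183, adjusted p = 0.809 with an estimated correlation). Of these calls 7 were lost on leaving out a single library. Without clean vehicle 3 the inflammatory median went to −0.00056 with camera's direction turned (camera adjusted p 0.953), and without infected vehicle 1 the call was lost (0.144). Without infected vehicle 2 the ribosomal protein median turned to −0.00112 (camera adjusted p 0.654), and leaving out clean vehicle 3, 4 or 5 or infected vehicle 5 ended that call (0.0899 to 0.29). Calls were also lost for fibroblast markers (without infected vehicle 1, camera adjusted p 0.114), heat shock genes (clean vehicle 1 or infected vehicle 4; 0.414 and 0.306), oxidative phosphorylation genes (clean vehicle 3 or 5, or infected vehicle 2; 0.136 to 0.865), G1/S genes (clean vehicle 3 or 5, infected vehicle 2 or 5; 0.0668 to 0.257) and antigen presentation genes (clean vehicle 3, 4 or 5, or infected vehicle 5; 0.0577 to 0.103). Interferon genes did not pass as a set (median −0.06, camera adjusted p 0.0785), with 1 fall adjusted over the list alone. The processed pseudogene score differed by 0.13 (n = 4, exact permutation p 0.257).

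The fifth comparison set infected against clean tumours under the drug. In infected STF tumours 2640 genes were higher and 4774 lower than in clean STF tumours. SEMA3A rose from 14.3 ± 3.46 CPM in clean to 63.4 ± 11.3 in infected tumours (2.13 ± 0.20, adjusted p 4.49e-05), and NAPRT1 from 48.9 ± 11.4 to 74.1 ± 9.85 CPM (0.59 ± 0.15, adjusted p 0.00535). NAMPT fell from 78.8 ± 21.9 to 58.6 ± 5.76 CPM (−0.43 ± 0.15, adjusted p 0.0346), and NNMT by 3.73 ± 0.67. POSTN fell from 406 ± 339 to 31.4 ± 4.03 CPM (−3.69 ± 0.44) and HSPA5 by 1.09 ± 0.21.

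The largest falls were in the cornified envelope gene SPRR1A (−5.70 ± 1.26), the keratins KRT76 (−5.68 ± 1.31) and KRT6C (−5.56 ± 1.09), SAA1 (−5.41 ± 1.04), CES1 (−5.31 ± 1.19), PLIN1 (−5.30 ± 1.02), the lipase LPL (−5.15 ± 1.04) and MYL4 (−4.97 ± 0.88). The largest rises, besides that of SEMA3A, were in GPR15 (2.24 ± 0.47), TNFSF18 (2.00 ± 0.47), TBX4 (1.90 ± 0.50), SNTG2 (1.65 ± 0.50), LRP1B (1.63 ± 0.21), ID3 (1.53 ± 0.23) and HIST1H1T (1.51 ± 0.33). ANXA10, one of the 5 genes named under vehicle, rose here (13.1 ± 1.51 and 35.4 ± 7.43 CPM, 1.43 ± 0.16), and SAMD9L, another of them, fell (9.96 ± 2.0 and 4.25 ± 0.308 CPM, −1.23 ± 0.21).

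All 18 fibroblast markers fell (median −3.33, camera adjusted p 2.21e-17, adjusted p = 0.769 with an estimated correlation), with PDGFRA at −3.82 ± 0.50. So did all 16 macrophage and neutrophil markers (median −2.89, camera adjusted p 3.77e-11, adjusted p = 0.769 with an estimated correlation). C1QB fell by 2.64 ± 0.37 and TYROBP by 3.04 ± 0.47. Of 12 endothelial markers 11 fell, or 11 with 1 rise adjusted over the list alone (median −2.86, camera adjusted p 9.01e-06, adjusted p = 0.769 with an estimated correlation), with CDH5 at −3.16 ± 0.49. Of the skin, muscle and fat markers 5 of 14 fell (median −2.19, camera adjusted p 0.00738, adjusted p = 0.769 with an estimated correlation). Lymphocyte and NK (median −0.84, camera adjusted p 0.347, 1 of 7 falling) and erythroid markers (−3.94, camera adjusted p 0.132, 3 of 4 falling) did not pass as sets. Processed pseudogenes fell in 987 of 1358 cases and rose in 18. The zinc finger score was higher by 0.61 (n = 4, exact permutation p 0.029).

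Proliferation genes rose beside that rise of the zinc fingers. Of 34 G1/S genes 29 rose, or 31 adjusted over the list alone (median 0.71, camera adjusted p 1.48e-11, adjusted p = 0.769 with an estimated correlation). E2F8 rose by 1.06 ± 0.22 and CDC6 by 0.77 ± 0.17. Of 36 G2/M genes 31 rose, or 35 adjusted over the list alone (median 0.73, camera adjusted p 3.17e-11, adjusted p = 0.769 with an estimated correlation). CENPA rose by 1.0 ± 0.24 and the proliferation marker MKI67 by 0.65 ± 0.17. With the zinc finger scaling 0 members of either list rose (medians 0.06 and 0.07), and MKI67 turned to −0.04. Histones rose in 14 and fell in 8 of 25 cases, or 17 and 8 adjusted over the list alone (median 0.81, mean −0.18, camera adjusted p 0.0731).

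Inflammatory genes fell in 18 of 33 cases and rose in 1, or 21 and 1 adjusted over the list alone (median −1.15, camera adjusted p 7.79e-05, adjusted p = 0.769 with an estimated correlation). The complement gene C3 fell by 4.15 ± 0.68, CSF1 by 1.62 ± 0.27 and NFKBIA by 1.15 ± 0.23. The receptors TLR4 (−3.20 ± 0.48) and TLR2 (−3.01 ± 0.50) fell, as did the stress regulators CEBPB (−0.99 ± 0.16) and NUPR1 (−2.84 ± 0.44). Lysosome genes fell in 12 of 26 cases, or 14 adjusted over the list alone (median −0.42, camera adjusted p 0.000688, adjusted p = 0.769 with an estimated correlation). LAMP2 fell by 0.70 ± 0.11 and CTSD by 0.89 ± 0.15. Chaperones of the endoplasmic reticulum fell in 8 of 20 cases, or 9 adjusted over the list alone (median −0.23, camera adjusted p 0.00968, adjusted p = 0.769 with an estimated correlation). EDEM1 fell by 0.98 ± 0.19. Mitochondrially encoded genes fell in 8 of 13 cases, or 12 adjusted over the list alone (median −1.07, camera adjusted p 0.000688, adjusted p = 0.769 with an estimated correlation). Hypoxia genes fell in 9 of 26 cases (median −0.33, camera adjusted p 0.0183, adjusted p = 0.769 with an estimated correlation). The collagen crosslinker LOX fell by 3.12 ± 0.45. The calls of the chaperones (clean STF 3, camera adjusted p 0.0752) and hypoxia genes (clean STF 1 or 4, or infected STF 2; 0.0991 to 0.143) were lost on leaving out a single library.

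Several lists lay higher under TMM but lower with the zinc finger scaling. These were cholesterol genes, with 3 of 25 rising, or 0 adjusted over the list alone (median 0.26 against −0.37, camera adjusted p 0.00925, adjusted p = 0.769 with an estimated correlation), and p53 targets, with 4 of 28 rising, or 1 adjusted over the list alone (0.21 against −0.39, camera adjusted p 0.0183, adjusted p = 0.769 with an estimated correlation). Oxidative phosphorylation genes rose in 8 and fell in 1 of 52 cases, or 0 adjusted over the list alone (0.21 against −0.45, camera adjusted p 0.0118, adjusted p = 0.804 with an estimated correlation), and ribosomal protein genes rose in 4 of 56, or 0 adjusted over the list alone (0.26 against −0.39, camera adjusted p 0.000387, adjusted p = 0.804 with an estimated correlation). Interferon genes rose in 1 and fell in 1 of 40 cases, or 0 and 1 adjusted over the list alone (0.21 against −0.43, and −0.20 without the 2 shallowest libraries, camera adjusted p 0.0492, adjusted p = 0.867 with an estimated correlation). FDFT1 (0.65 ± 0.20) and FDPS (0.51 ± 0.16), both of the cholesterol pathway, PARP1 (0.61 ± 0.19) and the intestinal transcription factor CDX2 (0.81 ± 0.20) rose, and FDPS, PARP1 and NAPRT1 turned negative with that scaling (−0.13, −0.06 and −0.03). NAD biosynthesis genes rose in 1 and fell in 7 of 19 cases, or 2 and 7 adjusted over the list alone (camera adjusted p 0.734). Without the 2 shallowest libraries NAMPT (−0.28), NAPRT1 (0.35), GPR15, SPRR1A, KRT76, CES1, NFKBIA and FDPS did not pass. Leaving out 1 library ended the calls of NAMPT, FDPS, PARP1 and SNTG2, and those of cholesterol genes (clean STF 2, camera adjusted p 0.0911), p53 targets (clean STF 2; 0.0845), oxidative phosphorylation genes (infected STF 5; 0.0738) and interferon genes (clean STF 2 or 4, infected STF 1 or 2; 0.0837 to 0.363). Without the 2 shallowest libraries 3765 genes passed (801 higher and 2964 lower), edgeR on the 8 STF libraries alone called 3839, limma voom called 4919, and the zinc finger scaling gave 57 higher and 10979 lower genes.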

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

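The tests on processed pseudogenes, on long intergenic non-coding RNAs of at least 1 CPM and on olfactory receptor genes were chosen only after the results they bear on were seen. So was the use of the fit of the 8 infected libraries alone to ask about the spread, while that fit and its regrouping were planned.

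Markers of fibroblasts, vessels and white blood cells rose with processed pseudogenes in clean STF tumours, with POSTN at 406 ± 339 CPM. Depth by itself is excluded as the cause for the fibroblast markers, since 18 of 18 still rose after every library was thinned to the smallest total. That test did not cover the other markers or the pseudogenes. Thinning could hardly hide changes of that size, and it does not show why some libraries were shallow. Genomic DNA would add reads to all exons alike, at most to the level of olfactory receptor genes, which most tissues do not transcribe. Those 379 genes together held 37.2, 38.8, 55.4 and 53.4 CPM in clean STF replicates 1 to 4 and 37.1 to 49.2 CPM in clean vehicle tumours. Per kb of exon, the median gain of markers over clean vehicle tumours was above the olfactory receptor level in each clean STF tumour, at the least by a factor of 133 for fibroblast, 24.6 for macrophage and neutrophil, 7.23 for endothelial, and 54.3 for skin, muscle and fat markers, all in replicate 3, so genomic DNA is excluded as the cause for these lists. A larger share of host (mouse) RNA counted on human genes may account for the pattern: the pseudogene score rose by 2.49 and the primate zinc finger score fell by 0.70 (n = 4, exact permutation p 0.029 for both). A test set beforehand was to speak against host RNA if long intergenic non-coding RNAs kept up with all genes, and they did (median gap −0.0054, interval −0.09 to 0.07). That test was poorly designed: most genes measured would come from tumour cells and be diluted alike (median −0.25 for the 14608 genes of at least 1 CPM in infected vehicle tumours), and 139 of the 236 RNAs lay under that level. The score of the other 97 was lower in all 4 clean STF than in all 4 clean vehicle tumours (−0.40, exact permutation p 0.029), though higher relative to the zinc fingers (0.31, exact permutation p 0.057), and their gap to all genes of that level was −0.10 (interval −0.29 to 0.01). Host RNA thus stays a candidate, and its share was not measured. Whether STF raised the host share at all, and if so by shrinking the tumour part or by drawing in host cells, was not tested and stays open.

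Cell cycle and interferon genes were lower in clean STF tumours (−1.17 and −0.95 in mean log2 CPM, n = 4, exact permutation p 0.029 and 0.057). Relative to the zinc fingers the cell cycle score changed by −0.47 (exact permutation p 0.114) and the interferon score by −0.25 (exact permutation p 0.4). Dilution of tumour RNA by host RNA and a fall within tumour cells cannot be told apart for these genes, because, although the cell cycle score fell by 0.47 more than the zinc fingers, neither difference from them passed with 4 tumours against 4. In infected STF tumours, where the zinc fingers changed by −0.10 (exact permutation p 0.2), the interferon score fell relative to them by 0.49 (exact permutation p 0.029), which could point to a change within tumour cells there and stays a hypothesis. The cell cycle score there changed by −0.37 relative to the zinc fingers and did not pass (exact permutation p 0.114).

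Few genes passed for STF in infected tumours in the shared fit (108). The fit of the 8 infected libraries alone called 3539, and limma voom, which gave clean STF replicates 2 and 4 weights of 0.167 and 0.248, called 4456. The spread of the clean STF libraries entering the shared fit may therefore hold the count down. How strong the response is in infected tumours was not settled by these counts, and a biological reading of the low count was not tested.

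Regrouping the libraries asked whether chance splits give as many genes, and 35 splits can exclude chance down to a share of 1 in 35 only. STF in clean tumours reached that share: 1 of 35 splits, the real one, gave as many genes (11554), and the highest of the others gave 2. STF in infected tumours reached it as well (108 genes, highest other 1), as did the fit of those 8 libraries alone (3539 genes, highest other 2). Mixed splits hold any real difference within their groups, which lowers their counts, so the gap to them adds nothing beyond that share. The count of 108 also fell to 0 without infected vehicle 1, 4 or 5. For the difference of the effects the test spoke to the grouping of the STF tumours only: 2 of 100 regroupings were as large as the real one (2774 genes, highest other 2978). The 3 others that left both STF groups whole and mixed the vehicle groups gave 2456, 2678 and 2978 genes and the remaining 96 at most 2, so this test did not settle what the vehicle groups add. For infection under vehicle chance was not excluded, since all 35 splits gave 0 genes, the real one included (0). For infection under STF 1 of 35 splits, the real one, gave as many genes (7414). The highest other split gave 5161 and put clean STF replicate 1 with infected STF replicates 1, 2 and 5, and another gave 2723. Wrong groupings thus gave many genes too, so this test does not exclude chance here beyond that share of 1 in 35.

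In 37 of 656 groups of 4 values, a single tumour lay apart from the other 3 by more than Dixon's critical share of the group's range. Chance gives about 1 in 20 groups, so the values that follow are about as many as chance alone would bring. Values of 1 library are not independent, so that count does not show that each library was typical. Infected STF replicate 4 recurs below, and its olfactory receptor genes held 69.7 CPM against 30.3 to 45.8 in the others of its group. Infected STF replicate 4 had 39690 genes detected, against 32411 to 33128 in the others of its group. In clean vehicle replicate 1 the mean log2 CPM was 5.73 for interferon genes, 5.14 for antigen presentation, 0.045 for intestinal differentiation and −0.81 for macrophage and neutrophil markers. The glycolysis score of clean vehicle replicate 5 was 8.69, the Wnt target score of infected STF replicate 1 was 4.72 and the lymphocyte score of infected STF replicate 4 was −0.078.

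For single genes, log2 CPM apart from the group in clean vehicle replicate 1 was 0.51 for C1QB, 7.95 for SAMD9, 6.74 for IFIT5 and −3.02 for TLR2. In clean vehicle replicate 3 it was −3.28 for S100A9, 5.14 for WNT16, 3.78 for NMNAT1 and 0.42 for IL1B. Clean vehicle replicate 4 had EGLN1 at 6.90, and clean vehicle replicate 5 had PCK1 at 0.69, FABP4 at 0.12 and FGF1 at 0.23. Clean STF replicate 1 had SUN3 at −0.59, and clean STF replicate 2 had GSTA4 at −2.68 and CSF1 at 4.92. Infected vehicle replicate 1 had TEK at 0.29 and HIST1H4I at 4.07, replicate 4 had CHL1 at −0.33 and FDPS at 6.19, and replicate 5 had SEMA3A at 6.02. Infected STF replicate 1 had GSTA4 at 0.62, replicate 4 had HP at 2.23, HPR at 3.51, WNT16 at 3.57, CCNE2 at 3.44, PLSCR1 at 6.10 and EPSTI1 at 3.02, and replicate 5 had HIST1H1T at 0.997 and CHL1 at 0.26.

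The effect of STF differed with infection, by the test of the difference itself, in 2774 genes. Of the negative calls 1039 were protein-coding genes and 752 processed pseudogenes, and of the positive calls 142 and 2. Host RNA, a candidate above for clean STF tumours, was not separated from a response of tumour cells here. The median difference of a list, infected minus clean, was −3.81 for fibroblast, −2.91 for endothelial, −2.96 for macrophage and neutrophil, and −2.21 for skin, muscle and fat markers. It was −0.47 for NF-kB and inflammatory genes, −0.34 for lysosome genes and −0.26 for hypoxia genes. It was 0.62 for G1/S, 0.68 for G2/M, 0.23 for p53 targets, 0.24 for interferon genes, 0.23 for cholesterol genes, 0.41 for heat shock genes and 0.20 for ribosomal proteins, and with the zinc finger scaling G1/S and G2/M shrank to 0.03 and 0.10 while the last 5 turned negative.

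Among named genes with a negative difference, those of muscle, fat and the acute phase measured −6.78 for MYL4, −5.47 for CA3, −5.18 for MYBPC1, −4.66 for NMRK2, −5.17 for PLIN1, −5.02 for FABP4, −4.73 for HP, −4.26 for HPR and −5.37 for SAA1. Matrix and vessel genes measured −5.62 for TNN, −4.21 for PDGFRA, −4.26 for POSTN, −3.98 for COL5A1, −4.18 for MMP2, −3.71 for CDH5 and −3.62 for TEK. Genes of white blood cells and receptors measured −2.52 for C1QB, −1.66 for ITGAM, −3.38 for TLR4 and −2.78 for CD14. The others were ZBTB16 (−5.32), LRRN1 (−5.36), NNMT (−4.40), HIST1H4I (−3.64), CHL1 (−2.97), LGR5 (−2.81), NUPR1 (−2.12), CEBPB (−1.07), HMOX1 (−0.98), CTSD (−0.92), EDEM1 (−0.85) and WIPI1 (−0.80). A positive difference was measured for GPR15 (2.55), LRP1B (1.94), PEG10 (1.61), SEMA3A (1.54), ID3 (1.45), GLIPR1L1 (1.41), GSTA4 (1.36), TMSB15A (1.19) and AXIN2 (0.91).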

How the results depend on the processing

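Leaving out clean STF replicates 2 and 4, thinning to the smallest library and scaling to the zinc fingers were chosen after the data were seen; the other alternatives were planned. For STF in clean tumours the count stayed within 1.5 times of 11554 under all alternatives run (7900 after thinning to 13137 with DESeq2; 10350 to 12884 leaving out 1 library), while its split did not: the zinc finger scaling gave 12794 rises and 189 falls. Of the named genes' values under alternatives, 3168 kept their side of the threshold, 323 lost and 63 gained a call and 8 turned sign. Of the lists' values 1951 kept their side, 184 lost and 62 gained a call and 4 turned, with the zinc finger scaling not among the set tests. Turns of sign were counted only where the main or the alternative value passed. With an estimated correlation 0 lists passed.

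For STF in infected tumours (108) the count was 64 with library totals alone, 46 with a stricter filter, 7 after thinning, 45 with the zinc finger scaling, 723 with the sample code as a covariate, 1150 with DESeq2, 3539 in the fit of both groups alone and 4456 with limma voom. Leaving out 1 library gave 0 (infected vehicle 1, 4 or 5) to 93 genes (infected STF 1). For the difference of the effects (2774) it was 1383 after thinning and 4408 with the zinc finger scaling, and 2068 (without infected vehicle 1) to 5359 (without clean STF 1) leaving out 1 library. For infection under vehicle (0) it was 5 in the fit of both groups alone, 8 with limma voom and 0 on leaving out any 1 library. For infection under STF (7414) it was 3839 in the fit of both groups alone, 4919 with limma voom and 3765 without the 2 shallowest libraries, and 6117 to 9597 leaving out 1 library. Thinned and smaller fits hold fewer counts or samples; the cause of the other shifts was not tested.

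With the replicate number as a replicate block, STF in infected tumours gave 20 genes and the difference of the effects 1812; the paired test of the response score kept the difference of 0.98 with an exact p of 0.125, the smallest that 4 pairs allow. For infection under vehicle the block left 7 lists past the threshold against 10 without it, with 5 calls lost and 2 gained. Named genes that lost their call numbered 5 of 19 for the difference and 14 of 37 for STF in infected tumours. Correlations between libraries that share a number lay between −0.13 and 0.34, and no label states that a number pairs tumours. Leaving out 1 library, the score difference was 0.84 to 1.11 (0.8440 to 1.1075), each with an exact p of 0.057 or above, the smallest possible there, and with the 100 genes of smallest p each way it was 1.60.

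With the zinc finger scaling the log2 change turned to 0.23 for NAPRT1, 0.15 for NMNAT1, 0.12 for NDUFB8 and 0.21 for UQCRFS1 under STF in clean tumours, and to −0.034 for NAPRT1, −0.038 for MKI67, −0.13 for FDPS and −0.064 for PARP1 for infection under STF; the scaling itself moved all genes. Without the 2 shallowest libraries the median of interferon genes turned to −0.17 for the difference of effects and −0.20 for infection under STF; the cause was not tested. Lists that passed went from 14 to 10 for the difference, with 3 calls lost besides that of interferon genes. For infection under STF they went from 16 to 15, with 3 others lost and 3 gained. For infection under vehicle, leaving out 1 library moved the median of inflammatory genes from −0.28 to −0.00056 (without clean vehicle 3, where camera's direction turned) and that of ribosomal protein genes from −0.00112 (without infected vehicle 2) to 0.12. Leaving out 1 library ended the calls of GSTA4, TMSB15A, CA3, SAA1, MYBPC1 and PLIN1 for the difference of effects, and of SNTG2, NAMPT, FDPS and PARP1 for infection under STF.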

Other observations

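Planned beforehand were the response score, the fit of the 8 infected libraries alone, the share in the 10 most abundant genes and the number of genes detected. The other tests described here were chosen after the data were seen. The score of histone genes, which are made as cells copy their DNA, was taken relative to the zinc fingers. It was higher in infected vehicle than in clean vehicle tumours by 0.29 (n = 4, exact permutation p 0.029, no overlap). Without that reference the difference was 0.29 with overlap (exact permutation p 0.057). Chance gives no overlap in 2.86% of such comparisons, and several scores were compared in this way. Relative to the zinc fingers the histone score was lower in infected STF than in infected vehicle tumours (−0.38, exact permutation p 0.029). In the fit of the 8 infected libraries alone, STF lowered 28 of 40 interferon genes, 22 of 34 G1/S genes, 20 of 36 G2/M genes, 13 of 25 histones and 11 of 20 antigen presentation genes, and raised 10 of 25 cholesterol genes while lowering 2.

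The response score was also made the other way round: the 1965 genes that rose and 1574 that fell with STF in the 8 infected libraries gave a score 3.0 higher in clean STF than in clean vehicle tumours (n = 4, exact permutation p 0.029). Relative to the zinc fingers, the falling part of this reverse score was −0.14 in clean tumours (exact permutation p 0.514), and the falling part of the first score was −0.24 in infected tumours (exact permutation p 0.086). With the 100 genes of smallest p each way these were −0.41 (exact permutation p 0.171) and −0.44 (exact permutation p 0.029).

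Clean STF tumours differed from clean vehicle tumours in the share of counts in the 10 most abundant genes (13.8 ± 3.33 against 9.28 ± 0.35%), in protein-coding genes (83.1 ± 4.35 against 89.7 ± 0.26%) and in small RNAs (9.04 ± 1.59 against 6.62 ± 0.51%), each with an exact permutation p of 0.029 (n = 4) and an adjusted p of 0.114. The number of genes detected was 33586 ± 4812 and 32663 ± 497 (n = 4, exact permutation p 0.686).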
